A study of Mus musculus with 2 samples.

How the data were processed

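NANOG ChIP-seq was done on 2 biological replicates of the mouse embryonic stem cell line E14TG2a.4, each with 1 technical replicate per the labels. Peak lists on genome builds mm9 and mm10 were used. The labels name a possible control experiment, which was not used here, and read depth per replicate is unknown. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here.

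The authors made 3 relaxed mm10 lists of 300000 regions each, for replicate 1, for replicate 2 and for the pool of both, as input to IDR, and derived an optimal and a conservative set from them. By the field order of the mm10 peak type, the deposited values per peak are a signal (an enrichment statistic of the peak caller whose scale is not stated), the -log10 of the q-value, an integer score of at most 1000 and the summit's offset. The authors' optimal set has signals from 7.30 to 675.8 with a median of 40.2, and 14 regions of it occur more than once with different summits. The deposited mm9 lists give an enrichment ratio per peak, whose reference is not stated, the -log10 of the p-value, and a q-value. The deposited q-value column of mm9 runs from 0 to 0.7227 and falls as the -log10 p-value rises, so it was read as untransformed. In the deposited mm9 lists, 53.2% of replicate 1 peaks, 29.3% of replicate 2 peaks and 0.0% of series-level peaks have a q-value above 0.05. How the authors combined the replicates into the series-level mm9 list is not stated. mm9 and mm10 coordinates were never compared with each other. Coordinates are printed as 1-based.

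Computation started from these lists, with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Peaks were ranked within a list by the authors' signal value on mm10 and by the enrichment on mm9. Gene positions on mm10 came from a GRCm38 gene table with 21883 protein-coding genes. On mm10, the TSS is the 5' end of the gene, with the strand taken by symbol or synonym from an mm9 gene annotation for 20558 of them (93.9%), which were the genes tested. The mm9 annotation, with 22156 protein-coding genes, and the mm9 genome sequence were used for exons and introns, motifs and chromosome lengths. The 17 gene lists hold 381 symbols, of which 369 could be measured. The lists, the 11 motifs, the tests and most alternatives were chosen before the data were examined.

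Replicate overlap was the share of top summits of 1 replicate within 100 bp of a top summit of the other, with as many peaks as the optimal set and with random placement on the same chromosome as the chance level. Coverage of the optimal and conservative sets was counted as sharing at least 1 bp with the top peaks of each replicate. A gene counted as having a peak when an optimal summit lay within 50 kb of its TSS, and each list was tested against all other protein-coding genes by Fisher's exact test. For locations, a site within 1 kb of a TSS was called a promoter site, then exon, intron and intergenic sequence in that order. For mm9 locations, the start of every annotated transcript of a protein-coding gene counted as a TSS. Centres of mm9 peaks, taken as the midpoints of the regions, were compared with 100000 random positions by the exact binomial test. Optimal mm10 summits were compared by Fisher's exact test with the lowest-ranked 100000 regions of the pooled relaxed list, of which 99975 lay on assembled chromosomes. For motifs, both strands of the sequence 50 bp to each side of the mm9 peak centre were searched, and the exact McNemar test compared them with windows of the same width 300 bp downstream. Motif content by rank was tested by Spearman's rho with 100000 permutations, and peaks per chromosome by the exact binomial test against assembled length. Peaks shared by the mm9 replicate lists and peaks of replicate 1 only were compared by Fisher's exact test and, within 50 strata of enrichment, by the Mantel-Haenszel test. Optimal peaks were joined into clusters and compared with 100 random placements. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the family named beside them, and an adjusted p under 0.05 counted as a call. Intervals of shares, and of ratios made from them, are exact Clopper-Pearson intervals at 95%. Those of Mantel-Haenszel odds ratios are 95% normal limits on the log scale.

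Genes were named by a rule fixed beforehand. It took the nearest TSS of the 20 highest optimal peaks within 500 kb of a TSS, up to 4 members of each list with the highest peak signal, up to 12 for the core list with all of its members that lack a peak, and the genes nearest to the 5 largest clusters. Genes outside it are marked in the text as chosen after their values were seen, and of the 20 highest peaks the text names only some.

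The design was written for mm10, but mm10 sequence, exons and chromosome lengths were not used here. Exon-level locations, motifs, motif content by rank and chromosome counts were therefore taken from the mm9 lists, a change made after the data were seen. Motif shares of conservative against other optimal peaks, the motif comparison with low-ranked mm10 regions, and the conservative-set alternative for motifs and chromosomes were not run for the same reason. Leaving out a replicate meant the top peaks of the other replicate alone on mm10, and the other replicate's own list on mm9. Other alternatives varied the peak set, overlap rule, distance, window, annotation, motif form, control and reference, and their effect is given with the closing observations. An odds ratio with no list member lacking a peak was computed with 0.5 added to each cell. No column was left out for lack of a sample, and 39 optimal peaks on unplaced scaffolds or the mitochondrial genome were left out of location tests.

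The code was tested on simulated data. Interval overlaps matched a brute-force count with 0 disagreements, and 100% of planted motif sites were found. For lists of 30 genes, Fisher's exact test made a call at an unadjusted p under 0.05 in 5.2% of simulations at the genome-wide share of 45.7%, in 28.4% at a share of 60%, in 77.2% at 70% and in 97.2% at 80%. For lists of 18 genes these were 3.0%, 21.0%, 56.0% and 88.2%, so smaller differences of short lists were often missed.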

Results

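NANOG, a homeodomain transcription factor of the pluripotency network, was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in E14TG2a.4, a male mouse embryonic stem cell line of strain 129/Ola. The labels give 1 group of 2 biological replicates, 1 antibody and an age of 3.5 days for both replicates, so no conditions were compared. The questions left by this design were where NANOG sites lie and how well the replicates share them. On mm10, each replicate and the pool of both had a relaxed list of 300000 ranked regions, made of peaks and background. The authors' reproducibility procedure (irreproducible discovery rate, IDR) left an optimal set of 15891 peaks and a stricter conservative set of 9431, with median widths of 364 bp. On mm9, replicate 1 had 22082 peaks, replicate 2 had 6618 and the series-level list had 13341. Read depth per replicate was not given in the sources used here and is unknown. The mm10 signal value is the authors' own and was used only to rank and describe peaks within a list. Intervals are exact 95% Clopper-Pearson intervals of shares of peaks or genes and cover counting error only. Peaks and genes of a list are not independent replicates, and sets that combine both replicates carry no replicate error.

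The strongest NANOG sites lay mostly outside promoters. The highest signal, 675.8, belonged to a peak 24.9 kb upstream of Kdm5b, a histone H3K4 demethylase (mm10 chromosome 1, 134534993 to 134535465, outside any protein-coding gene). The next was 99.9 kb upstream of Gclm, a subunit of the enzyme that starts glutathione synthesis, and inside the gene Abca4 (chromosome 3, 122145318 to 122145816, signal 630.9). The peak nearest to Ism2 lay 18.3 kb upstream of it and inside Sptlc2 (chromosome 12, 87317947 to 87318377, signal 629.2). A peak 46.1 kb upstream of Klf9, a zinc-finger transcription factor, had signal 566.8 (chromosome 19, 23094904 to 23095307). Among the 10 highest peaks, the closest to a transcription start site (TSS) lay 2.23 kb upstream of Rax, a homeobox gene of the eye field (chromosome 18, 65941131 to 65941538, signal 502.0). Others of these 10 were nearest to Vwa3b, Adora2b, Siah3 and Ttc25. All 20 highest peaks were in the conservative set and were overlapped by the top peaks of each replicate. Over 15852 optimal peaks on assembled chromosomes, the median distance from summit to nearest protein-coding TSS was 44.3 kb (quartiles 13.7 and 136 kb), and 52.9% lay within 50 kb.

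The replicates shared their strong sites and parted at weaker ones. Of the 500 highest-ranked summits of replicate 1, 78.4% (74.5 to 81.9) lay within 100 bp of a summit among the 500 highest of replicate 2. The share was 74.1% (72.7 to 75.5) at 4000 peaks, 64.6% (63.6 to 65.7) at 8000 and 46.2% (45.4 to 46.9) at 16000. With as many peaks as the optimal set, 7376 of 15891 summits of replicate 1 were shared, 46.4% (45.6 to 47.2), and the reverse share was 46.4%. Summits placed at random on the same chromosomes gave 0.164%. The share fell to 20.9% when 50000 peaks were taken from each replicate.

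**Figure D1:**
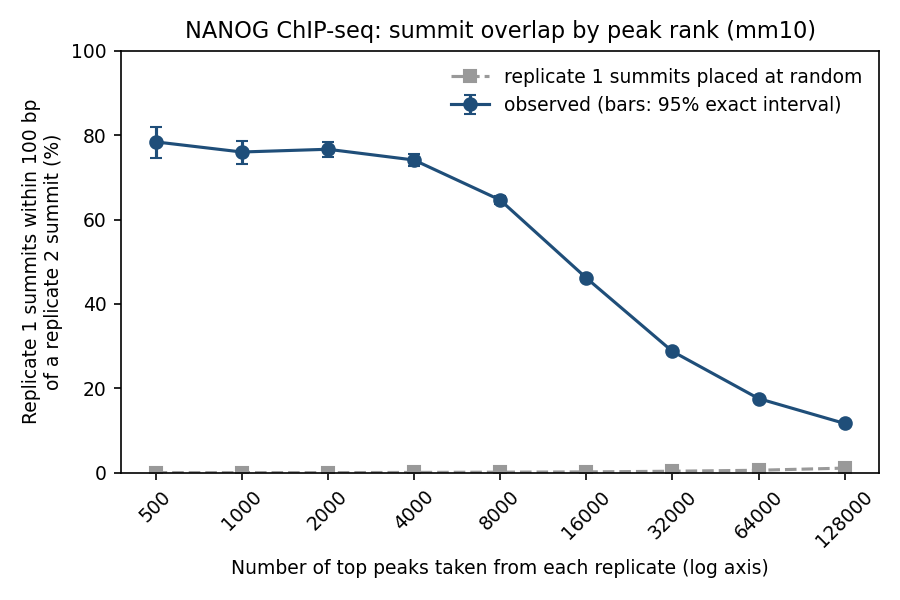
Share of replicate 1 summits within 100 bp of a replicate 2 summit (%), against the number of top peaks taken from each mm10 list (log axis), with exact 95% intervals as bars and randomly placed summits in grey. The share is 78.4% at 500 peaks and 17.6% at 64000, where random placement gives 0.564%.

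Replicate 1 recovered more of the final sets than replicate 2. Top peaks of replicate 1 overlapped 86.3% (85.8 to 86.8) of optimal peaks, and those of replicate 2 overlapped 54.6% (53.9 to 55.4). For the conservative set the shares were 94.9% (94.4 to 95.3) and 90.6% (89.9 to 91.1). Both sets were derived from these same lists, so high shares are in part built in. The conservative set was not wholly inside the optimal set, as 419 of its peaks (4.44%) overlapped no optimal peak. Both replicates overlapped 8012 optimal peaks (50.4%), and neither overlapped 1505 (9.47%). With the whole relaxed list of replicate 2, its share of the optimal set was 84.9%. The mm9 lists, called for each replicate on its own, were nested: 98.7% (98.4 to 99.0) of replicate 2 peaks overlapped a replicate 1 peak, but only 29.2% (28.6 to 29.8) of replicate 1 peaks overlapped a replicate 2 peak. The 15626 replicate 1 peaks without a partner had a median enrichment of 7.93, and the 6456 with a partner had 21.8. Their median q-values were 0.173 and 0.0027. The highest q-value was 0.7227 in the list of replicate 1 and 0.2983 in that of replicate 2. Limited to lists of equal length, 77.7% of replicate 1 peaks and 78.7% of replicate 2 peaks overlapped the other list.

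Genes of the core and naive pluripotency network were more often near NANOG peaks than other genes. Of the 30 genes of this list, 28 had an optimal peak within 50 kb of the TSS, 93.3% (77.9 to 99.2), against 45.7% of all other protein-coding genes. This share was the highest of the 17 lists with the optimal set, but without replicate 1 Hox genes (89.7%), FGF signalling (85.0%) and WNT signalling (84.0%) were above the core list (83.3%). Without replicate 2 it was level with the polycomb list (86.7% each), and within 100 kb the primed and Hox lists (100% each) were above it (96.7%). Pou5f1, which encodes OCT4, had a peak of signal 314.3 at 0.930 kb upstream of its TSS (mm10 chromosome 17, 35504957 to 35505263). Klf2, Prdm14 and Tfcp2l1, transcription factors of naive pluripotency, had peaks of signal 312.3 at 15.4 kb downstream, 307.1 at 42.1 kb downstream and 256.5 at 2.28 kb upstream of their TSSs. Dppa5a, a pluripotency marker gene, had a peak of signal 287.1 at 6.98 kb upstream, and Tcf7l1, a repressor at WNT-controlled genes, had a peak of signal 225.6 inside the gene. Peaks of Myc, Zfp281, Sall4, Rif1, Tbx3 and Fbxo15 had signals between 134.6 and 221.3, and the 12 genes named from this list had their peaks in the conservative set and in the top of both replicates. The 2 members without a peak in the window were Esrrb, an orphan nuclear receptor whose nearest peak lay inside the gene 105 kb downstream of the TSS (chromosome 12, 86466164 to 86466527, signal 29.3) and which had 1 peak in the window in replicate 2 alone, and Stat3, the transcription factor downstream of the cytokine LIF, with the nearest peak 51.7 kb upstream. Nanog itself, chosen after its values were seen, had 2 peaks in the window, or 4 in the top peaks of replicate 2 alone and 3 in those of replicate 1 alone. The higher of these optimal peaks lay 4.88 kb upstream of its TSS (chromosome 6, 122702538 to 122702628, signal 59.6). By Fisher's exact test, two-sided, the odds ratio of the core list was 16.7 (p = 5.17e-08, adjusted over 17 lists 8.79e-07). It was 4.72 without replicate 1 and 7.68 without replicate 2, with the adjusted p between 4.62e-14 and 0.00214 over all alternatives.

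Genes of chromatin regulation were near NANOG peaks as well. In the list of polycomb and other chromatin genes, 25 of 30 had a peak, 83.3% (65.3 to 94.4; odds ratio 5.94, exact p = 2.88e-05, adjusted p = 0.000245). The odds ratio ran from 3.85 at 10 kb to 7.68 without replicate 2. Jarid2, an accessory subunit of polycomb repressive complex 2, had a peak of signal 336.1 at 2.12 kb upstream of its TSS (chromosome 13, 44728477 to 44728847). Mtf2 and Aebp2, other accessory subunits of that complex, had peaks of signal 185.5 and 181.3. Pcgf6, a subunit of a variant polycomb repressive complex 1, had a peak of signal 266.5 at 32.8 kb downstream, inside the gene Ina. The 5 members without a peak, named after their values were seen, were Rnf2, Ring1, Pcgf1, Cbx2 and Chd4, of which the first 4 encode subunits of polycomb repressive complex 1.

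Of the other developmental and signalling lists, 3 passed the test after adjustment. BMP and Nodal signalling had 19 of 25 genes with a peak (76.0%, odds ratio 3.76, exact adjusted p = 0.0166), among them Id3, a target of BMP signalling, with signal 384.8 at 3.13 kb downstream of its TSS. Lefty1 and Lefty2, antagonists of Nodal, shared a peak of signal 318.0 (chromosome 1, 180924676 to 180925063), and Acvr1b, an activin receptor, had a peak of signal 268.1 inside the gene. Neuroectoderm had 14 of 17 genes (82.4%, odds ratio 5.54, exact adjusted p = 0.0154), but the signals of its highest members were lower, at 95.6 for Nes, 75.4 for Pax3, 66.1 for Lhx2 and 64.8 for Nkx6-1. Hox genes had 26 of 39 with a peak (66.7%, odds ratio 2.38, exact adjusted p = 0.0331). A single peak of signal 158.1 (chromosome 2, 74672554 to 74672799) lay within 50 kb upstream of the TSSs of Hoxd3, Hoxd4, Hoxd8 and Hoxd9. Since Hox genes lie in 4 clusters, their p-value is too small. The neuroectoderm call was lost with the conservative set (odds ratio 1.54), without replicate 1 (2.26), in windows of 10 kb (3.14) and 100 kb (7.86) and with mm9 peaks (2.53), and the BMP and Nodal call without replicate 1 (2.43), at 100 kb (3.60) and with mm9 peaks (2.45). The odds ratio of Hox genes was higher without replicate 1 (8.27), without replicate 2 (5.40), with the conservative set (4.42) and at 100 kb (38.9, computed with 0.5 added to each cell). Hox genes lost the call at 10 kb (2.26) and turned to fewer than other genes when each summit counted only for its nearest TSS (0.415); adjusted p ran from 0.00024 to 0.555, 9.92e-05 to 0.0981 and 5.22e-06 to 0.0583 over the alternatives of these 3 lists.

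The remaining 12 lists did not pass the test. Primed and formative pluripotency genes had 14 of 19 with a peak (73.7%, odds ratio 3.32, exact adjusted p = 0.055), but this list did pass in all alternatives except those without off-assembly peaks and without other listed genes in the background, among them without replicate 1 (3.54) and without replicate 2 (3.30). Its adjusted p lay between 9.92e-05 and 0.055 over the alternatives. Its highest peaks were at Foxd3, a forkhead factor of the epiblast (signal 443.0), Fgf5, a marker of the epiblast (374.8), Otx2 (334.0) and Zic2 (244.3). DNA methylation genes had 13 of 18, with signals of 484.6 for Mbd2, a methyl-CpG-binding protein (28.0 kb upstream, with the TSS of Poli nearer at 5.28 kb), 322.6 for Tet2 and 279.0 for Tet3, both enzymes that oxidise methylcytosine, and 232.3 for Uhrf2. FGF signalling had 14 of 20, WNT signalling 16 of 25 and LIF signalling 10 of 16. Il6st and Lifr, which encode the receptor chains for LIF, had peaks of signal 318.9 and 284.4, Dkk1 and Lgr4 of the WNT list 357.4 and 288.1, and Fgfr2 and Spred1 of the FGF list 268.3 and 189.3. The FGF and WNT lists passed without replicate 1 (odds ratios 5.35 and 4.96), within 10 kb (5.77 and 2.71), by nearest TSS (5.71 and 4.05) and with gene bodies plus 50 kb (3.49 and 2.76), and not without replicate 2 (2.75 and 2.10). The FGF list also passed with the conservative set (5.15) and with mm9 peaks (4.14). The LIF and primitive endoderm lists passed within 10 kb (3.46 and 4.61) and by nearest TSS (5.71 and 2.99), DNA methylation within 10 kb (4.61) and with gene bodies (4.37), and trophectoderm by nearest TSS (3.17). Mesoderm had 11 of 18 with a peak, trophectoderm 8 of 16, primitive endoderm 9 of 18, germline 8 of 18, housekeeping 13 of 28, and liver, muscle and blood 10 of 29. Genes of the 2-cell-like state had the lowest share with the optimal set, 2 of 12 (16.7%, 2.09 to 48.4), with an odds ratio of 0.237 and an adjusted p of 0.0884 by Fisher's exact test. It was below the other genes without replicate 1 (0.188) and with gene bodies plus 50 kb (0.238), but not without replicate 2 (0.393) or with mm9 series-level peaks (0.613), with the adjusted p from 0.0479 to 0.699 over the alternatives. The liver, muscle and blood list was below them without replicate 2 (0.245) and with mm9 series-level peaks (0.287), where its share (17.2% in both) was the lowest of the lists, with the adjusted p from 0.00948 to 1.0.

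**Figure D2:**
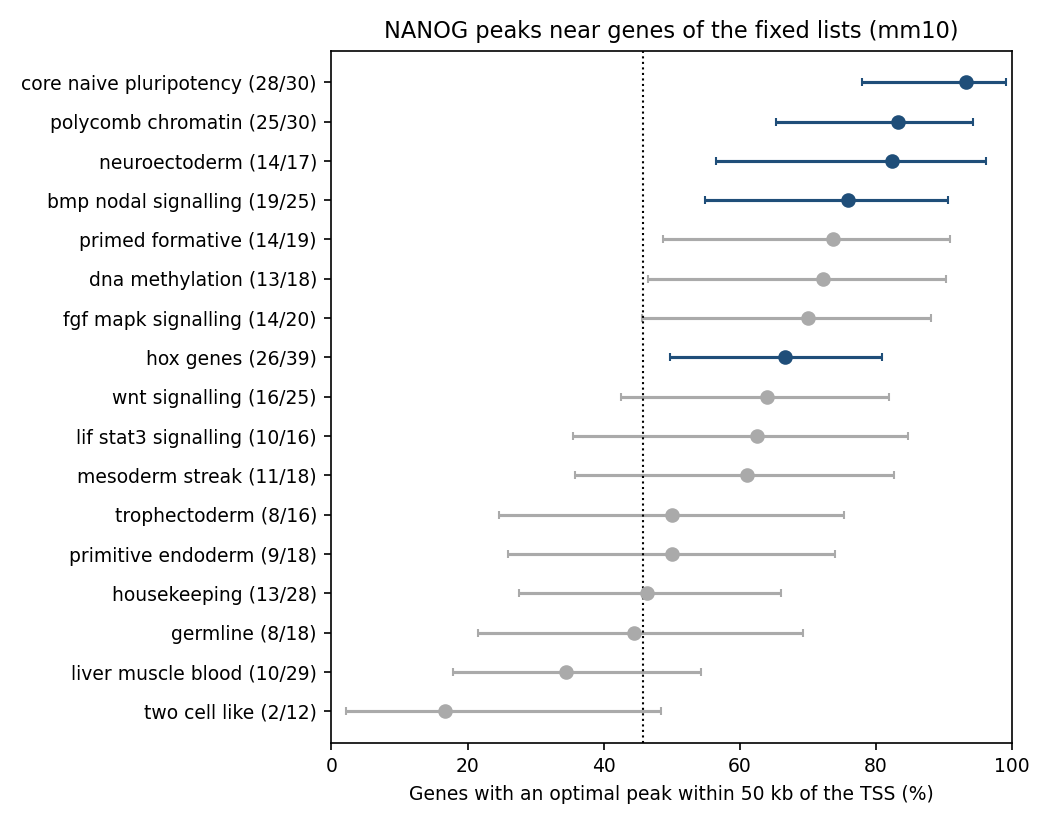
Share of genes with an optimal NANOG peak within 50 kb of the TSS (%) in each of the 17 gene lists, with exact 95% intervals and the number of genes with a peak over the number measured. The dotted line is the share of all genes, 45.7%, and the 5 lists in blue passed Fisher's exact test after adjustment.

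NANOG sites were mostly distal, with more at promoters and in introns than random positions. Of 13341 series-level mm9 peak centres, 56.2% (55.3 to 57.0) were intergenic, 37.2% (36.4 to 38.1) were in introns, 4.74% (4.38 to 5.11) lay within 1 kb of a protein-coding TSS and 1.86% (1.64 to 2.10) were in exons. Random positions gave 60.6%, 34.0%, 3.14% and 2.29%. Promoters were 1.51 times as frequent as in the genome (exact binomial test, two-sided, adjusted p = 1.12e-22), introns 1.095 times (5.44e-15), exons 0.812 times (0.000703) and intergenic sequence 0.927 times (1.48e-24). The exon call was lost without replicate 1 (0.884). The promoter ratio was 1.18 with mm9 peaks of q at most 0.001 (exact binomial adjusted p = 0.0452) and 1.83 without replicate 2. On mm9 each transcript start counted as a TSS here, and on mm10 only the 5' end of the gene. On mm10, 3.15% of optimal summits and 2.76% of the lowest-ranked 99975 relaxed regions lay at promoters, an odds ratio of 1.15 (Fisher's exact test, adjusted p = 0.00563), and gene bodies held 44.3% against 48.5% (0.842, adjusted p = 3.33e-23). This promoter excess was lost with a promoter of 500 bp to each side (1.13), with the conservative set (0.948), without replicate 1 (0.957) and without replicate 2 (1.097), and the difference in gene bodies was lost without replicate 1 (0.976).

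Optimal peaks that were also in the conservative set were less often at promoters than the rest of the optimal set. Of optimal peaks that overlapped the conservative set, 2.57% lay at promoters, against 3.92% of those that did not, an odds ratio of 0.647 (Fisher's exact test, two-sided, p = 1.73e-06, adjusted over 3 classes 5.19e-06). Gene bodies held 44.3% and 44.2% (exact adjusted p = 0.949). The overlapping peaks numbered 9014, with a median signal of 60.9, and the other 6877 had a median of 27.3. Promoter shares were not compared at like signal, so the difference cannot be told apart from one of peak strength.

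DNA motifs of several pluripotency factors were more frequent at the centres of NANOG peaks than 300 bp away. The mm9 series-level peaks had a median width of 853 bp, and their centres are midpoints, not summits. Most windows 300 bp away therefore lay inside the same peak, and a bound site can lie outside the central window. Within 50 bp of the centre on each side, a joint SOX2 and OCT4 site (up to 2 mismatches) lay in 195 of 13341 mm9 series-level peaks, 1.46% (1.26 to 1.68), against 0.135% in windows 300 bp downstream, a ratio of 10.8. Of these sites, 0 matched the full 15 bp consensus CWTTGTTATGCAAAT, 22 had 1 mismatch and 173 had 2. The OCT octamer was 3.81 times as frequent (4.37% against 1.15%), the SOX site 3.05 times (15.1% against 4.94%) and the ESRRB site 3.44 times (3.02% against 0.877%). Sites of the KLF family, which includes KLF2 and KLF4, were 1.82 times as frequent (1.05% against 0.577%) but only 1.35 times as frequent as in windows 300 bp upstream (0.780%, exact McNemar adjusted p = 0.039, from 7.81e-10 to 0.0495 over the alternatives). They were spread broadly: in bins of 50 bp, the highest share, 0.690%, was in the bin that starts at -150 bp, against 0.540% in the bin that starts at 0. By the exact McNemar test adjusted over 11 motifs, p was 3.41e-39 for the joint site, 1.8e-60 for the octamer, 9.44e-170 for SOX, 1.16e-37 for ESRRB and 4.16e-05 for KLF. Over the alternatives the ratio ran from 6.25 (q of at most 0.001) to 24.4 (windows 300 bp upstream) for the joint site, from 2.93 to 5.26 for the octamer, from 2.57 to 4.04 for SOX and from 2.15 to 6.11 for ESRRB. The short NANOG site TAATKK was at 21.8% (21.1 to 22.5) against 20.1%, a ratio of 1.09 (exact adjusted p = 0.000843). In bins of 50 bp, its share was 12.1% in the bins that start at -50 and 0 bp. It was 9.68% in the bin that starts at -150 bp and 11.8% in the bin that starts at -1000 bp. Against random windows of the same GC count, 16.2% of which held the site, the ratio was 1.34 (exact adjusted p = 1.42e-30). The call against windows 300 bp downstream was lost without replicate 2 (1.02), with windows reaching 100 bp to each side (1.03) and with the mm9 peaks of q at most 0.001 (1.08), and the adjusted p ran from 1.42e-30 to 0.297 over the alternatives. The stricter form TAATGG gave 6.85% against 4.00%, a ratio of 1.71. An octamer of the form ATGCTAAT before GG, GT, TG or TT also holds a TAATKK site, and such overlaps were not removed.

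The STAT site was 1.60 times as frequent at centres (0.480% against 0.300%, exact adjusted p = 0.0307), a call lost without replicate 1 (1.88), in the narrower window, against the upstream control and at q of at most 0.001, with the adjusted p from 1.35e-05 to 1.0 over the alternatives. The GATA site of endoderm and blood regulators was less frequent at centres, 1.66% against 2.22% (ratio 0.747, exact adjusted p = 0.00146). The TFCP2L1 site (ratio 1.15), the PRDM14 site (0.857) and the site of the insulator protein CTCF, in 11 peaks at centres and in 10 at 300 bp downstream, did not differ by this test. The TFCP2L1 site did pass it without replicate 2 (1.21), against windows 2000 bp downstream (1.27) and against random windows of the same GC count (1.26), with the adjusted p from 0.0332 to 0.825 over the alternatives. The CTCF site passed it without replicate 2 alone (2.25, adjusted p from 0.0326 to 1.0), where the peaks are those of replicate 1.

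**Figure D3:**
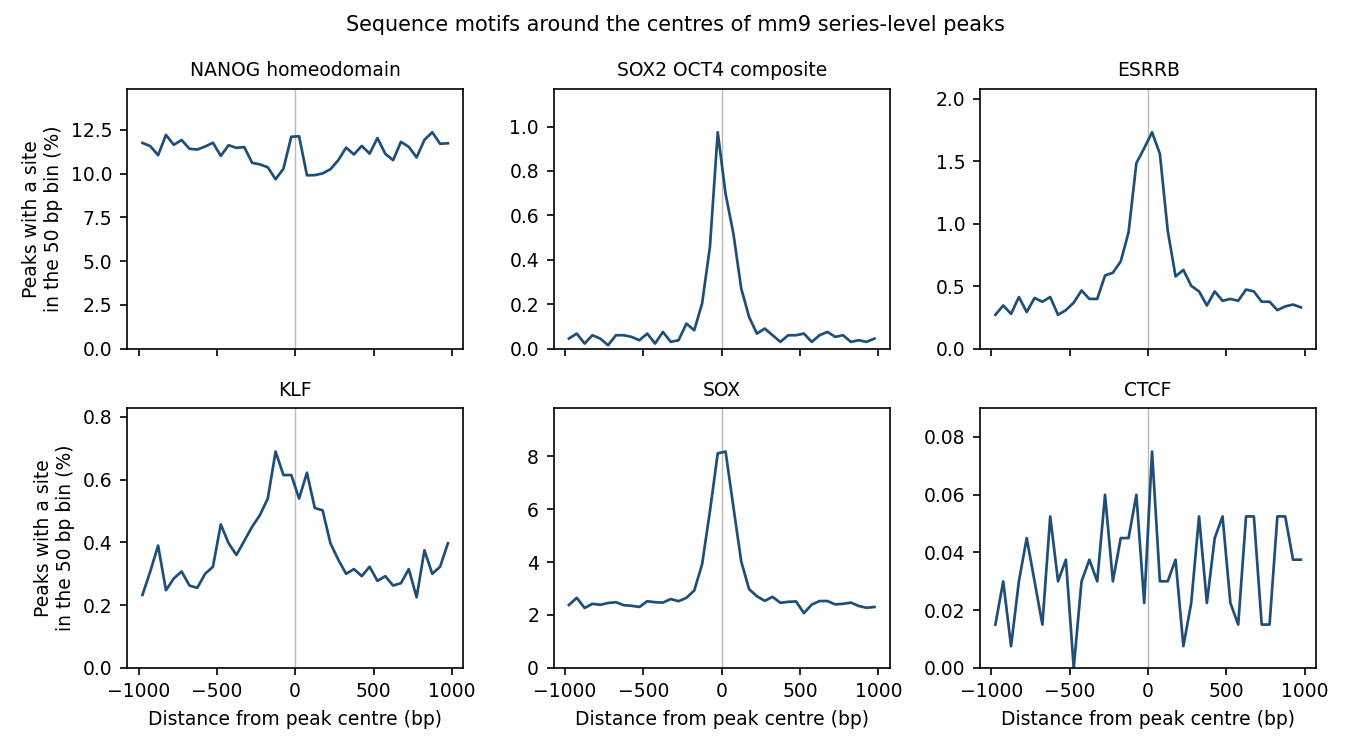
Share of 13341 mm9 series-level peaks with a motif site in bins of 50 bp (%), against the distance of the bin from the peak centre in bp, each panel with its own scale from 0. The SOX2 and OCT4 joint site, the SOX site and the ESRRB site rise at the centre, and the NANOG site varies between 9.68% and 12.4% across the window.

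The peak with the highest enrichment among those with a joint SOX2 and OCT4 site lay 11.8 kb upstream of Slain2, in intergenic sequence (mm9 chromosome 5, 73293194 to 73294270, enrichment 44.5). Its site, CTTTCTTATGCAAAT, spans 73293761 to 73293775 and has 1 mismatch, within the sequence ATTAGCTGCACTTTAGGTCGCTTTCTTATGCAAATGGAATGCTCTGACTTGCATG. Of the 195 peaks with such a site, 113 were intergenic, 69 in introns, 10 at promoters and 3 in exons. Of the 195, 2 had a core pluripotency gene within 50 kb, and the share among all series-level peaks was not counted. Both genes are named here after their values were seen. Both sites have 2 mismatches. The site CATTGTGATGCATAT lay in a peak centred 4.08 kb downstream of the TSS of Sox2 (site at chromosome 3, 34552971 to 34552985, peak enrichment 7.22). The site CTCAGTTATGCAAAT lay in a peak centred in the promoter of Zfp42, which encodes the pluripotency marker REX1 (site at chromosome 8, 44392535 to 44392549, peak enrichment 5.37).

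Motif content differed with peak strength, in opposite directions for different motifs. NANOG sites lay in 23.6% (22.0 to 25.3) of the fifth of mm9 peaks with the highest enrichment and in 19.9% (18.4 to 21.5) of the fifth with the lowest. Octamers lay in 4.95% (4.15 to 5.84) and 3.45% (2.79 to 4.21). ESRRB sites went the other way, at 2.14% (1.62 to 2.76) and 3.45% (2.79 to 4.21), as did STAT sites, at 0.262% (0.106 to 0.540) and 0.750% (0.458 to 1.16). Across peaks, Spearman's rho between enrichment and the presence of a site was 0.0290 for NANOG (permutation p = 0.0007, adjusted over 11 motifs 0.00193), 0.0317 for SOX (adjusted p = 0.00158), 0.0244 for the octamer (0.0103), -0.0314 for ESRRB (0.00158) and -0.0297 for STAT (0.00158). It was 0.00455 for the joint SOX2 and OCT4 site (0.733). Ranked by the p-value column instead, the relations of the NANOG site (rho 0.0120, permutation adjusted p = 0.448), the SOX site (0.0120, 0.448) and the octamer (0.00786, 0.5) no longer passed, and those of ESRRB (-0.0348, 0.00066) and STAT (-0.0241, 0.0284) did.

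The X chromosome carried few NANOG peaks. It held 315 of the mm9 series-level peaks, 2.36% against 6.28% of the assembled length, a ratio of 0.376 (0.336 to 0.419; exact binomial test, two-sided, adjusted over 21 chromosomes p = 2.65e-98). Chromosome 11 carried the most for its length, with a ratio of 1.27 (1.18 to 1.36; exact adjusted p = 3.64e-10), and chromosome 7 carried fewer (0.898, adjusted p = 0.00626), a call lost when only sequenced bases counted as length (0.930). In all, 8 chromosomes lay above their share and 4 below. On the Y chromosome there was 1 peak, a ratio of 0.0125 to assembled length, 0.0710 (0.00180 to 0.395) to sequenced bases and 0.0977 to protein-coding genes, with 6 peaks in the list of replicate 1 alone and 0 in that of replicate 2. Counts per protein-coding gene were a reference chosen after the data were seen. By them, chromosomes 11 (0.783), 17 (0.861) and 19 (0.858), all above their share of length, turned to fewer peaks than their share. Chromosome 12, below its share of length (0.911), turned to more (1.32). Chromosome 9 lost its call (0.929 against 1.12 by length), and X stayed low (0.566). Chromosome 7 was as low as X by this reference (0.555, exact binomial adjusted p = 2.35e-69). On mm10, where lengths were not used, X held 2.62% of optimal and 2.52% of conservative peaks, and 0.957% of the pooled relaxed list.

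**Figure D4:**
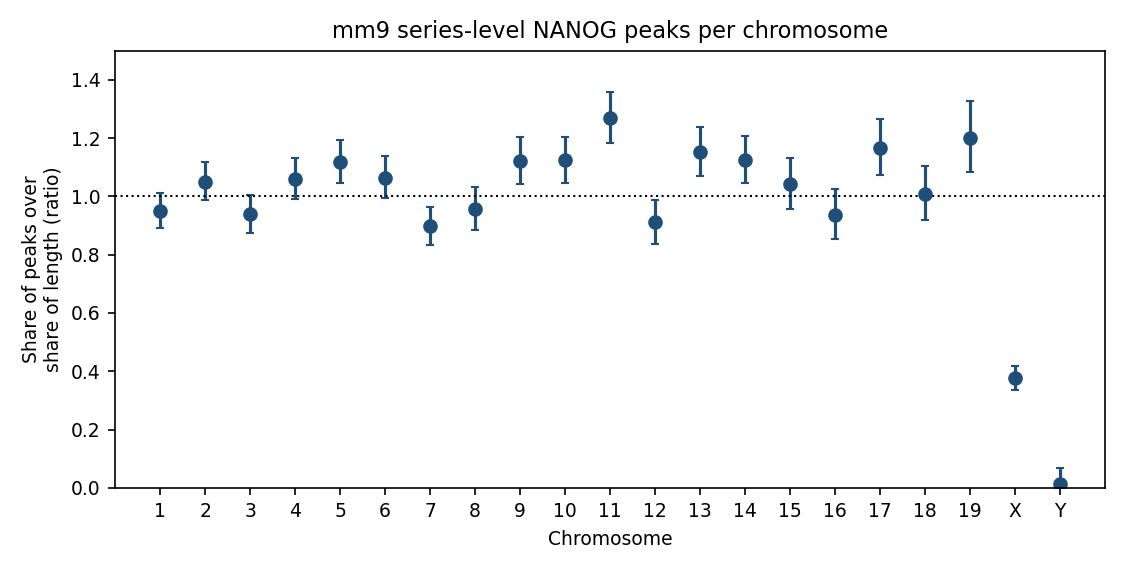
Share of mm9 series-level NANOG peaks over the share of assembled length for each chromosome (ratio), with exact 95% intervals as bars. The X chromosome lies at 0.376 and Y at 0.0125, and chromosome 11 has the highest ratio, 1.27.

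Some NANOG peaks lay in dense clusters. Joined at a distance fixed beforehand, between the alternatives of 5 kb and 25 kb, the optimal peaks made 12555 clusters, of which 48 held at least 5 peaks. Random placements on the same chromosomes gave 0.750 such clusters on average and 3 at most over 100 placements. A cluster of 9 peaks inside Myo10, with Retreg1 as the nearest TSS, spanned 49.4 kb (mm10 chromosome 15, 25724504 to 25773865). Another of 9 overlapped Nlrp12 (chromosome 7, 3193117 to 3228364), and 8 peaks lay at Epha4, an ephrin receptor (chromosome 1, 77440473 to 77457308). Clusters of 7 lay inside Btbd11 and near Tuba1a, an alpha-tubulin gene. The number with at least 5 peaks was 19 without replicate 1, 31 without replicate 2 and 10 in the conservative set. It was 10 with joining at 5 kb and 142 with joining at 25 kb.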

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

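The test of gene density on the X chromosome was chosen only after its result was seen. The other tests of explanations were fixed before their results were seen.

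The optimal set held 39 peaks off the assembled chromosomes, in sequence that the location, gene, motif and chromosome comparisons did not use; they were counted in the overlaps between sets. Of these, 12 lay on the mitochondrial genome, with a median signal of 67.2 and a highest signal of 135.1, and 23 lay on the unplaced scaffold JH584304, with a median of 36.9. The remaining 4 lay on 3 other unplaced scaffolds. Of the mitochondrial peaks, 9 were in the conservative set, and the top peaks of replicates 1 and 2 overlapped 8 and 9. Of those on JH584304, 15 were in the conservative set, and the top peaks of replicates 1 and 2 overlapped 15 and 21.

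Replicate 1 had 22082 mm9 peaks and replicate 2 had 6618. These lists reach q-values of 0.7227 and 0.2983, so the numbers are not counts at a common q-value. The median q-value was 0.173 in peaks of replicate 1 only and 0.0027 in those shared with replicate 2. The tables argue against regions without bound sequence as the whole of the extra peaks: at centres of the 15626 peaks found in replicate 1 only, the joint SOX2 and OCT4 site was 9.0 times as frequent as 2000 bp away (1.09% against 0.122%). The short NANOG site itself was not called there, 20.2% against 20.9% (ratio 0.970, exact McNemar adjusted p = 0.194), nor in the replicate 1 peaks shared with replicate 2 (1.06, adjusted p = 0.127). At centres of the 6618 peaks of replicate 2 it was called against windows 300 bp downstream. There it was at 24.3% against 19.5% (ratio 1.25, exact McNemar adjusted p = 4.69e-11). Ratios to windows at 2000 bp and at 300 bp are not directly comparable. Against windows 300 bp downstream, all 22082 replicate 1 peaks gave 1.02 (exact McNemar adjusted p = 0.297). Of replicate 2 peaks, 98.7% overlapped a replicate 1 peak, so most of these sites are the same. Their centres came from narrower regions, with a median width of 562 bp against 832 bp in replicate 1. How many of the extra peaks of replicate 1 are bound stays open. Of the 8500 top mm10 summits of replicate 1 on assembled chromosomes that the top of replicate 2 missed, 37.7% lay within 100 bp of a region in the relaxed list of replicate 2, against 3.20% after a shift of 10 kb, a ratio of 11.79. Weaker enrichment or lower depth in replicate 2 at the same sites is therefore a candidate explanation, and the remaining summits stay unexplained. No biological explanation was tested, since the labels give no difference between the replicates.

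The X chromosome held 2.36% of mm9 peaks against 6.28% of the length. Lower gene density is argued against as the whole cause, since the share of peaks was 0.5656 times the share of protein-coding genes (4.17%, exact binomial p = 8.29e-30). A low share per gene was not particular to X, since chromosome 7 was at 0.555 by this reference, though at 0.898 by length. A single X copy in a male cell could lower the detection of weak sites, which would make the deficit smaller among strong peaks. The length-based ratio was 0.298 in the fifth of peaks with the highest enrichment and 0.233 in the fifth with the lowest, a ratio of 1.282 (Fisher's exact p = 0.285). In the bins between them it was 0.478, 0.496 and 0.376, from higher to lower enrichment, so the deficit was not smallest among the strongest peaks (interval 0.222 to 0.392, against 0.396 to 0.612 in the middle bin), and it did not change steadily with strength. On mm10, X held 2.62% of optimal and 2.52% of conservative peaks but 0.957% of the pooled relaxed list, which goes the way that a loss of weak sites would, although that list also holds background. A single copy could also lower the enrichment by which peaks were ranked, since the reference of that value is not stated. The mm9 values did not change steadily with strength, and the relaxed mm10 list holds background as well. The part of a single copy in the deficit therefore cannot be told apart from other causes. A biological difference between X and the autosomes was not tested.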

How the results depend on the processing

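Alternatives with mm9 gene positions, gene bodies, distant or GC-matched motif controls, a q-value limit, gene counts as reference, or without off-assembly peaks or other listed genes, were chosen only after the data were seen; the cause of each change listed was not tested, except that shorter or longer lists change overlap by construction. The overlap of top summits, 46.4%, was 36.78% at 50 bp, 50.74% at 500 bp, 50.44% for regions sharing 1 bp, 42.32% for regions sharing 50%, 60.63% with as many peaks as the conservative set and 20.88% with 50000 peaks. Optimal peaks covered by replicates 1 and 2 were 83.71% and 51.95% when 50% had to be covered, and 99.79% and 84.94% with whole relaxed lists. On mm9, overlap of replicate 1 by replicate 2 and the reverse were 21.33% and 71.15% for regions sharing 50%, and 77.65% and 78.72% at equal length.

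The mm10 promoter odds ratio, 1.15, was 0.9483 in the conservative set, 1.13 with a promoter of 500 bp and 0.9566 to 1.097 without a replicate. Without a replicate, gene bodies ranged from 0.8415 to 0.9756, other sequence from 1.03 to 1.175, and mm9 exons from 0.8721 to 0.8842. All other mm9 location calls held in the alternatives run. The mm9 promoter ratio nevertheless ran from 1.18 at q of at most 0.001 to 1.83 without replicate 2. The 5 gene lists called above other genes became 9 at 10 kb, 10 by nearest TSS and 9 with gene bodies. Between 4 and 6 were called in the other alternatives, and Hox genes reversed by nearest TSS (0.4154). Of single lists, 30 results gained a call and 9 lost it, and 155 results, summary counts included, kept their side. Core and polycomb lists kept their calls in each alternative run.

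For the NANOG motif, the ratio of 1.09 was 1.031 with windows of 100 bp to each side, 1.085 at q of at most 0.001, 1.342 against random windows of the same GC count and 1.021 to 1.247 without a replicate, and its relation to rank was 0.01203 by the p-value column. The joint SOX2 and OCT4, octamer, SOX, ESRRB and KLF motifs kept their direction in all motif alternatives, though the ratio of the joint site ran from 6.25 to 24.4 and that of ESRRB from 2.15 to 6.11. Chromosomes 11 (0.7835), 12 (1.32), 17 (0.861) and 19 (0.858) reversed per gene, and X stayed below its share throughout. Clusters with at least 5 peaks were 10 in the conservative set, 10 at 5 kb, 142 at 25 kb and 19 to 31 without a replicate. Peaks counted near single named genes changed in 141 recounts with another peak set (48 up, 93 down) and did not in 144. The unknown read depth limits what the lower number of peaks in replicate 2 can show, and 2 replicates give only a poor estimate of spread. No paired analysis was possible because there was only 1 group.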

Other observations

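The tests between shared peaks and peaks of replicate 1 only, the number of genes with many peaks and the count of peaks with both kinds of site were chosen only after the data were seen.

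Peaks found in replicate 1 only differed from those shared with replicate 2 in location and motif content, but no such difference was detected between peaks of like strength. Of the 15626 replicate 1 mm9 peaks without a partner, 6.34% (5.96 to 6.73) lay within 1 kb of a protein-coding TSS, against 4.35% (3.87 to 4.88) of the 6456 shared peaks (odds ratio 1.49, Fisher's exact test, two-sided, adjusted over 15 features p = 5.88e-08). They more often carried an ESRRB site at the centre, 3.12% against 2.37% (odds ratio 1.33, exact adjusted p = 0.0132), and a KLF site, 1.45% against 0.991% (1.47, adjusted p = 0.0237). The short NANOG site was less frequent in them, 20.2% against 21.7% (0.914, exact adjusted p = 0.039), and the joint SOX2 and OCT4 site did not differ by this test, 1.09% against 1.36% (adjusted p = 0.212). The comparison was then made within 50 strata of equal size by enrichment, of which 47 held both kinds of peak, with 15184 and 5572 peaks. The Mantel-Haenszel odds ratio was 0.910 (0.740 to 1.12) for promoters, 1.04 (0.798 to 1.37) for ESRRB, 0.756 (0.504 to 1.14) for KLF and 0.938 (0.842 to 1.04) for the NANOG site. For the joint site it was 0.744 (0.509 to 1.09), against 0.801 without strata. By the Mantel-Haenszel test, adjusted over the 15 features, 0 passed, and 0 were under 0.05 before adjustment. The odds ratio of the NANOG site changed little from 0.914, so its lost call does not show that strength accounts for the difference.

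Spry4 and Etv5 of the FGF list, which did not pass the test as a whole, had many peaks within the window; both were singled out after their counts were seen, and no group of genes was tested. Spry4, an inhibitor of receptor tyrosine kinase signalling, had 10 optimal peaks within 50 kb of its TSS, and 9 in the conservative set, with a highest signal of 149.2 at 30.5 kb downstream (mm10 chromosome 18, 38570734 to 38570965). Etv5, a transcription factor induced by FGF signalling, had 8, and 7 in the conservative set, with a highest signal of 135.0 inside the gene. Of 20558 genes tested, 4 had at least 10 optimal peaks in this window and 21 had at least 8. Counts in the top peaks of single replicates were 11 and 10 for Spry4 and 8 and 8 for Etv5.

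Of the 195 mm9 series-level peaks with a joint SOX2 and OCT4 site, 50 also had a TAATKK site within 50 bp of the centre. That site lay in 21.8% of all series-level peaks, and the difference was not tested. A joint site that ends in TAAT before GG, GT, TG or TT holds a TAATKK site by itself. Part of the 50 is therefore set by the motif definitions, and such overlaps were not removed.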
